A study of Mus musculus with 8 samples.

How the data were processed

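RNA was measured by low-input sequencing in GPR35-positive and GPR35-negative macrophages (MHCII+CD64+) sorted from the colonic lamina propria of 4 male mice, so that 8 libraries fell into 2 groups of 4. Per the labels' protocols, epithelium was stripped with EDTA, the tissue was digested with collagenase and DNase, the populations were sorted into Trizol, and RNA was extracted with a micro kit. Per the labels' protocols, cDNA was amplified with SMART-Seq v4 and libraries were made with Nextera XT, a method that does not mark strand and uses no molecular identifiers. PCR copies are then counted as reads, so intervals on shares of counts cover counting error only. Reads from a gene and an antisense or overlapping partner cannot be told apart.

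The deposited table holds raw read counts per gene, with whole numbers that sum to different totals in each library and a gene length column that was not used. Per the submitters' processing notes, STAR 2.5.2a, R 3.4.2 and the mm10 build were used; the counting tool and its annotation are not given in the sources used here. The table lists 14980 genes, of which 9 carried no symbol and held 0.0179% of the counts. Each listed gene reached at least 18 counts and 0.885 CPM in some library, so genes below a low-count limit are not analysed here. The table as used here has 0 mitochondrially encoded genes, and the mitochondrial share planned among the library measures was not computed. Totals are therefore totals over the listed genes. Entrez gene IDs were matched to the GRCm38.p6 annotation, from which coordinates were taken; 14944 matched.

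Counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14193. Libraries were scaled by TMM, and a robust quasi-likelihood F-test compared the groups with no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are GPR35-positive minus GPR35-negative, with SE taken as the size of the fold change over the square root of F. CPM values use TMM effective library sizes and are given as mean ± SD over 4 libraries, and log2 CPM per library used a prior count of 2. The CPM of Xist and Ddx3y, the limit of 0.885 CPM and the filter of 5 CPM use library totals without TMM factors. Shares of counts are percentages of each library's total over the listed genes.

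The gene lists, 31 in all, were tested with limma 3.58.1 by camera with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. None of the camera calls held with an estimated correlation. Of the list genes, 43 symbols were not among those in the table. A count "adjusted over the list alone" repeats the adjustment of the gene tests over that list's members. Library measures were compared with 2-sided exact permutation tests in Python 3.11.15 (scipy 1.17.1 for the exact binomial interval). With 4 libraries against 4 these have 70 arrangements and cannot go below p = 0.0286 in the exact permutation test, and flipping signs within the 4 animals has 16 arrangements and cannot go below an exact p = 0.125.

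The samples, the test, the lists, the rule for named genes and the other settings to try were fixed before the data were examined. The rule named Gpr35; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 3 log2 CPM and 1 direction in all 4 animals; up to 4 members with the smallest p of each list that passed camera or had a member past the threshold; and Tnf, Il10, Il1b, Cx3cr1 and Ccr2. Genes named outside it are marked as chosen after their values were seen.

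The labels give the same animal number to a GPR35-positive and a GPR35-negative sample, so the numbers pair the libraries. The deviations of paired libraries from their group means correlated across genes at 0.205, 0.206, 0.432 and 0.0637 for replicates 1 to 4. The highest correlations with a library of another animal were 0.104, 0.0913, 0.172 and 0.237, so the own partner was not the closest for replicate 4. Genes are not independent replicates. The fit without the animal block was set as the main one because no model is stated in the labels, and the fit with the replicate block was an alternative. No pair of libraries in a group agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 26.6.

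Other settings fixed then were RLE, library-size and upper-quartile scaling, no count filter, a filter of at least 5 CPM in 4 libraries, DESeq2 1.42.0 with and without the block, limma voom with quality weights, no robust estimation, and leaving out each animal or library. Settings added after seeing the data scaled every library to the geometric mean of the macrophage identity list, with and without the block, thinned every library to the smallest total, and used the animals of replicates 1 and 2 alone. The test was checked on simulated counts with the libraries' own sizes and spread and no animal effects, over 14000 genes. It recovered 0%, 24%, 60% and 92% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, and 5.38% of its calls were false. With simulated animal effects, over 13987 genes, these shares were 0%, 0%, 30% and 88%.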

Results

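GPR35 is a G protein-coupled receptor that responds to lysophosphatidic acid and kynurenic acid, among other ligands. The series asked how colonic macrophages that carry it differ from those that do not. Macrophages positive for MHC class II and CD64, the high-affinity Fc gamma receptor, were sorted by GPR35 staining from the lamina propria of 4 male mice, each of which gave both populations. Total counts over the listed genes were 42.5 ± 6.38 M in the GPR35-positive libraries (SD, n = 4), with a range of 33.8 to 48.6 M. In the GPR35-negative libraries they were 23.6 ± 6.10 M, with a range of 16 to 30.1 M. The totals were higher in the positive library of all 4 animals. The 2-sided exact permutation p was 0.0286, the smallest it can give, and did not pass after adjustment over 4 library measures (0.114). The exact sign-flip p within animals was 0.125, also the smallest possible. Ribosomal protein genes took 0.662 ± 0.111% of counts in positive and 0.925 ± 0.170% in negative libraries (exact permutation p = 0.0571, adjusted 0.114), and the 50 highest genes 29.8 ± 1.29% and 27.8 ± 2.38% (exact permutation p = 0.171, adjusted 0.229). Genes with a count numbered 14350 ± 557 and 14390 ± 431 (exact permutation p = 0.886). The ribosomal RNA precursor Rn45s, chosen after its values were seen and not tested, took 0.166 ± 0.031% of counts in positive libraries. In negative libraries it took 0.348 ± 0.060%, and the ranges did not overlap (0.146% to 0.212% and 0.297% to 0.431%).

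Gpr35 (Entrez gene 64095, chromosome 1, 92948052 to 92986391 in GRCm38.p6, protein coding) was at 73.3 ± 14.8 CPM in the GPR35-positive and 2.97 ± 1.46 CPM in the GPR35-negative libraries (SD, n = 4), higher in the positive library of all 4 animals. The log2 fold change was 4.60 ± 0.39 (SE; edgeR adjusted p = 1.07e-04), and 2.10 with every library scaled to the macrophage identity genes, a scaling chosen after the data were seen. The exact permutation p was 0.0286 and the exact sign-flip p within animals 0.125, each the smallest possible.

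**Figure D1:**
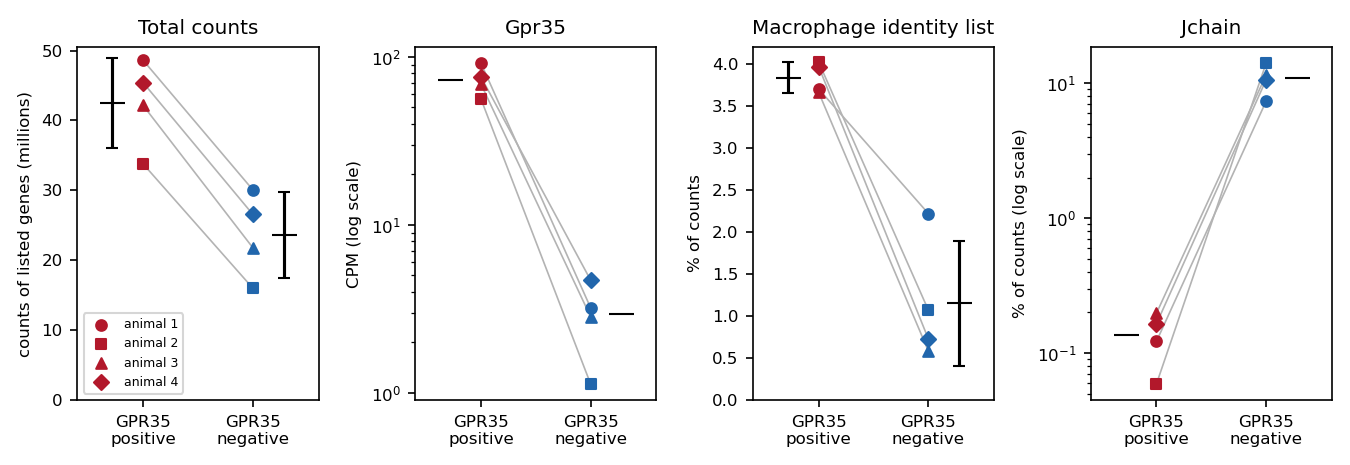
Total counts, Gpr35 CPM, the share of counts in the macrophage identity list and the share of Jchain in each library, with lines joining the 2 populations of an animal; black marks show group means, with SD on the linear axes. Jchain took 0.136% of counts on average in the GPR35-positive and 10.9% in the GPR35-negative libraries, while the identity list took 3.84% and 1.15%.

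Between the populations, 5387 of 14193 tested genes passed the threshold, 2613 higher and 2774 lower in GPR35-positive cells, and 5318 of them differed in 1 direction in all 4 animals. At least 2-fold differences were seen for 1545 higher and 2006 lower genes. Among the largest increases were H2-M2, a non-classical MHC class I gene (206 ± 106 against 2.48 ± 1.28 CPM; log2 fold change 6.38 ± 0.55), Itgax, which encodes the integrin CD11c (427 ± 41.4 against 7.42 ± 5.22 CPM; 5.85 ± 1.0, with GPR35-negative replicate 4 at 0.033 CPM), Mefv, which encodes pyrin (5.72 ± 0.88), and Mmp12, macrophage elastase (5.70 ± 0.65). Treml4 (6.05 ± 1.02), Stra6l (5.91 ± 0.71), Gpr141 (5.71 ± 0.65) and Htr7, a serotonin receptor (5.28 ± 1.09), were also among them, as were the predicted gene Gm19434 (5.61 ± 0.66) and Ccl22 (5.54 ± 1.34), whose call ended without replicate 4 (edgeR adjusted p = 0.0625). Ccl22 also lost its call with limma voom (adjusted p = 0.361) and with identity scaling (2.62, adjusted p = 0.200), and Htr7 with limma voom (adjusted p = 0.0617). Among the largest decreases were genes known from plasma cells, Mzb1 (-6.19 ± 0.48), Tnfrsf17, the BCMA receptor (-6.09 ± 0.34), Pou2af1 (-6.09 ± 0.54) and Ccr10, a homing receptor (-6.24 ± 0.53). Prg2 (-6.20 ± 0.51), an eosinophil granule gene, and Slpi (-6.20 ± 0.59), a protease inhibitor, stood with them, with Mgat3 (-6.44 ± 0.90), Ly6k (-6.42 ± 0.93), Fut1 (-6.34 ± 1.08) and the non-coding Kcnmb4os2 (-6.19 ± 0.76). With library size as the only scaling, 1690 genes were higher and 4193 lower. Scaled to the identity genes, 84 were higher and 11957 lower. Under that scaling 32 of the 140 named genes changed sign, whether or not the new value was past the threshold. The scaling moved the median of all genes from -0.05 to -2.51. Genes with smaller increases turn negative through that common shift, here and in the paragraphs below. Without replicate 3 the count was 3281 and without replicate 4 it was 3306.

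**Figure D2:**
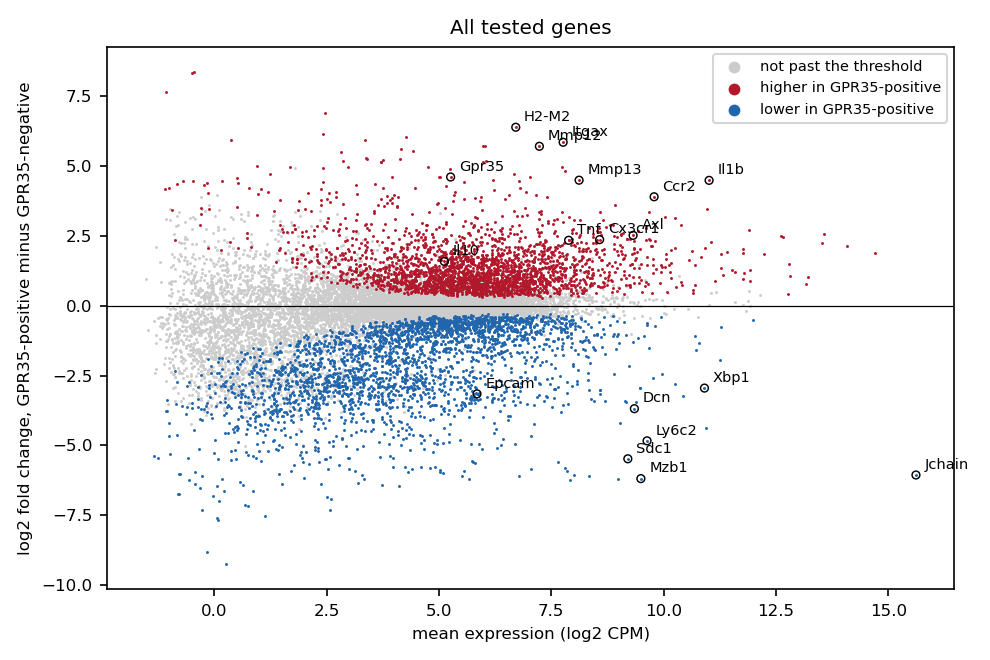
Log2 fold change of each tested gene, GPR35-positive minus GPR35-negative, against its mean expression in log2 CPM; each point is a gene, colored by whether it passed the threshold (2613 higher, 2774 lower), and circled genes are named. With libraries scaled to the macrophage identity genes 11957 genes lay significantly lower, and Tnf was at 0.44 and Il10 at -0.88.

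B and plasma cell, T and innate lymphoid, stromal, epithelial, and glial and erythroid lists were lower in GPR35-positive cells, while granulocyte and dendritic cell lists did not pass. Jchain (chromosome 5, 88519809 to 88527897), the joining chain of polymeric immunoglobulin, made up 10.9 ± 2.79% of counts in the GPR35-negative libraries, 7.37% to 14.1% per library, against 0.136 ± 0.060% in the GPR35-positive libraries. Of 14 tested B and plasma cell genes 12 were lower and 1 higher in GPR35-positive cells (12 and 1 adjusted over the list alone). The latter, Prdm1, was chosen after its values were seen, and the former included Jchain (log2 fold change -6.06 ± 0.44), the plasma cell marker Sdc1 (-5.48 ± 0.28) and the secretory transcription factor Xbp1 (-2.95 ± 0.15). The median of the list was -5.32 (camera adjusted p = 8.97e-18, and adjusted p = 0.296 with an estimated correlation). Stromal, endothelial and muscle genes were lower for 17 of 24 (22 adjusted over the list alone; median -2.77, camera adjusted p = 1.90e-07; adjusted p = 0.367 with an estimated correlation). Among them were Dcn (-3.69 ± 0.41), Lum (-3.56 ± 0.42) and Gsn (-1.57 ± 0.17). T and innate lymphoid cell genes were lower for 14 of 20 (16 adjusted over the list alone, and 9 with the replicate block; median -2.63, camera adjusted p = 9.68e-07; adjusted p = 0.356 with an estimated correlation). Among them were Cd28 (-4.65 ± 0.17) and Cd2 (-4.18 ± 0.45). Glial, neuronal and erythroid genes were lower for 7 of 13 (8 adjusted over the list alone, and 11 with the replicate block; median -2.96, camera adjusted p = 5.28e-03; adjusted p = 0.451 with an estimated correlation). Those with the smallest p were hemoglobin genes, near-identical copies that counting can split; Hbb-bt, at -3.00 ± 0.69, lost its call without replicate 2 (edgeR adjusted p = 0.0614) and without replicate 4 (0.0579). Epithelial genes were lower for 6 of 22 (4 adjusted over the list alone; median -1.37, camera adjusted p = 9.60e-03; adjusted p = 0.502 with an estimated correlation). Epcam was at -3.16 ± 0.25 and Lypd8 at -1.90 ± 0.41. With identity scaling, under which the median of all genes was -2.51, the epithelial and glial medians were -4.08 and -5.62 and their calls ended (camera adjusted p = 0.489 and 0.554). Granulocyte and mast cell genes did not pass as a list (2 higher, 5 lower of 14, and the same counts adjusted over the list alone; median -1.54, camera adjusted p = 0.176).

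Macrophage identity genes were higher in GPR35-positive cells for 18 of 20 (18 adjusted over the list alone), and the list took 3.84 ± 0.183% of counts against 1.15 ± 0.742%. Examples were the receptor tyrosine kinase Axl (log2 fold change 2.52 ± 0.30), the transcription factor Spi1 (2.08 ± 0.33) and the signaling adaptors Fcer1g (2.14 ± 0.35) and Tyrobp (2.38 ± 0.40). The median was 2.04 and, scaled to the list itself, 0.03 (camera adjusted p = 1.59e-08, and adjusted p = 0.367 with an estimated correlation). Genes of mature colonic macrophages were higher for 19 of 22 (20 adjusted over the list alone), with a median of 1.98 that became -0.01 with identity scaling (camera adjusted p = 1.66e-11, and adjusted p = 0.296 with an estimated correlation). They included Acp5 (3.06 ± 0.17), Dtx4 (2.51 ± 0.30), Itgav (2.67 ± 0.34) and Dnase1l3 (4.42 ± 0.47). With identity scaling 3 of the 22 were past the threshold as higher and 4 as lower, and Dnase1l3 stayed higher (2.13, edgeR adjusted p = 1.39e-03). Among genes of incoming monocytes 10 of 19 were higher and 2 lower (11 and 3 adjusted over the list alone), with a median of 1.91 that became -0.48 with identity scaling (camera adjusted p = 0.0288, and adjusted p = 0.367 with an estimated correlation). The chemokine receptor Ccr2 was at 1656 ± 259 against 111 ± 117 CPM (3.90 ± 0.70, edgeR adjusted p = 3.22e-03) and Ms4a4c was higher (2.83 ± 0.26). In contrast, Ly6c2, a marker of newly arrived monocytes that plasma cells also express, was lower (-4.84 ± 0.24). The monocyte call ended without GPR35-negative replicate 1 (camera adjusted p = 0.0516) and with the filter of 5 CPM (0.137). Long-lived resident macrophage genes did not pass as a list (2 higher, 3 lower, 15 not past the threshold of 20, with 2 and 3 adjusted over the list alone; median -0.23, camera adjusted p = 0.95). Its medians were -1.81, -0.79, 1.14 and 0.63 in replicates 1 to 4. Cd4 was higher (1.83 ± 0.28) and the scavenger receptor Colec12 lower (-2.66 ± 0.57). The fractalkine receptor Cx3cr1 was at 638 ± 190 against 124 ± 124 CPM (2.36 ± 0.64, edgeR adjusted p = 0.0186), a call that ended without replicate 2 (0.0798), without replicate 4 (0.0817) and without GPR35-negative replicate 2 (0.0556). With identity scaling Spi1 (-0.0539) and Cd4 (-0.37) turned negative, and Axl, Fcer1g, Tyrobp, Acp5, Dtx4, Itgav, Ms4a4c and Cx3cr1 (0.56, adjusted p = 0.244) lost their calls. In the same libraries Jchain and other plasma cell genes were lower in GPR35-positive cells.

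**Figure D3:**
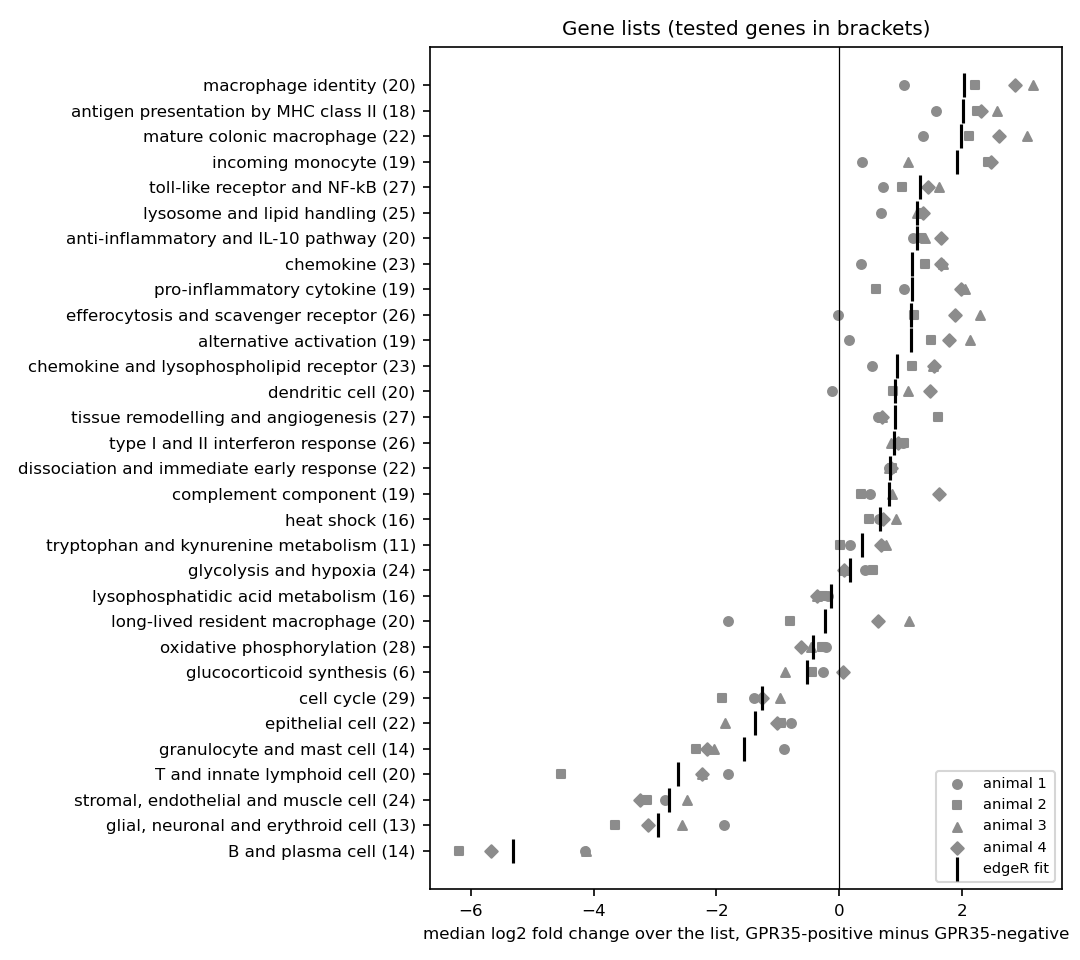
Median log2 fold change of each preset list, GPR35-positive minus GPR35-negative, in each animal (gray symbols) and in the edgeR fit (black bars), with the number of tested genes in brackets. The macrophage identity, mature and monocyte lists lie to the right, the long-lived resident list at -0.23, and B and plasma cell genes farthest to the left at -5.32; with libraries scaled to the identity genes, the median of each list other than macrophage identity was below 0.

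Cytokine and sensing lists had medians above 0 in GPR35-positive cells, and below 0 with identity scaling. Il1b (chromosome 2, 129364569 to 129371164), which encodes interleukin-1 beta, was at 3954 ± 951 against 177 ± 125 CPM (log2 fold change 4.48 ± 0.52, edgeR adjusted p = 4.10e-04), and it stayed higher with identity scaling (2.47). Il1a (4.14 ± 0.25) and Ptgs2, cyclooxygenase-2 (3.02 ± 0.53), were higher and Csf1, the macrophage growth factor, lower (-2.24 ± 0.24). Of 19 tested pro-inflammatory cytokine genes 10 were higher and 2 lower (10 and 3 adjusted over the list alone), with a median of 1.18 that became -0.92 with identity scaling (camera adjusted p = 1.90e-03, and adjusted p = 0.296 with an estimated correlation). Tnf was at 394 ± 62.9 against 77.9 ± 64.3 CPM (2.34 ± 0.57, edgeR adjusted p = 0.0125), a call that ended without replicate 2 (adjusted p = 0.055) and with identity scaling (log2 fold change 0.44, adjusted p = 0.367). Anti-inflammatory and IL-10 pathway genes were higher for 15 of 20 (16 higher and 1 lower adjusted over the list alone), with a median of 1.26 that became -1.01 with identity scaling (camera adjusted p = 7.19e-07, and adjusted p = 0.296 with an estimated correlation). GPR35-positive replicate 1 stood at a mean of 7.89 log2 CPM for this list, against 7.45 to 7.47 in the others. Il10 was at 51.9 ± 17.3 against 17.3 ± 5.19 CPM (1.58 ± 0.30, edgeR adjusted p = 4.11e-03), and at -0.88 with identity scaling. The interleukin-1 decoy receptor Il1r2 (3.83 ± 0.37) and antagonist Il1rn (3.88 ± 0.45) were higher, as was Socs3 (1.86 ± 0.28). Toll-like receptor and NF-kB genes were higher for 16 of 27 (19 adjusted over the list alone), with a median of 1.32 that became -0.85 with identity scaling (camera adjusted p = 1.13e-05, and adjusted p = 0.367 with an estimated correlation). These included Tnip3 (2.97 ± 0.26), Myd88 (1.61 ± 0.19) and Irak4 (1.41 ± 0.20). Interferon response genes were higher for 13 and lower for 2 of 26 (13 and 2 adjusted over the list alone), with a median of 0.89 that became -1.47 with identity scaling (camera adjusted p = 4.38e-04, and adjusted p = 0.413 with an estimated correlation). Irf8 (2.04 ± 0.24) was among the former and Bst2 (-2.08 ± 0.32), which plasma cells express, among the latter. Chemokines did not pass as a list (10 higher, 3 lower of 23, and 10 and 3 adjusted over the list alone; camera adjusted p = 0.0971), but passed with the replicate block (adjusted p = 0.0462; 0.554 with an estimated correlation), without replicate 1 (1.71e-03), without GPR35-positive replicate 1 (0.0405) and without GPR35-negative replicate 1 (4.55e-03). Their median of 1.18 became -1.15 with identity scaling, which placed them above other genes (camera adjusted p = 1.32e-03). Cxcl16 was higher (3.16 ± 0.47) and Cxcl12 (-3.29 ± 0.34) and Ccl11 (-3.61 ± 0.33), which stromal cells make, lower. Receptors for chemokines and lysophospholipids had 9 higher and 6 lower of 23 (12 and 8 adjusted over the list alone; camera adjusted p = 0.0677), with a median of 0.93 that became -1.37 with identity scaling. They passed with the block (0.0370; adjusted p = 0.415 with an estimated correlation), without replicate 1 (0.0326), without replicate 4 (0.0492), and without GPR35-negative replicate 1 (0.0344) or 4 (0.0488), and under 5 other settings of scaling or filter. Lpar6, a lysophosphatidic acid receptor (1.85 ± 0.19), Ccr1 (2.58 ± 0.35) and Cxcr4 (2.24 ± 0.36) were higher. With identity scaling Socs3 (-0.42), Myd88 (-0.72), Irak4 (-0.95), Irf8 (-0.21) and Lpar6 (-0.47) turned negative, and Ptgs2, Tnip3, Ccr1 and Cxcr4 lost their calls. In the same libraries stromal genes, at a median of -2.77, and Jchain, at -6.06, were lower in GPR35-positive cells.

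**Figure D4:**
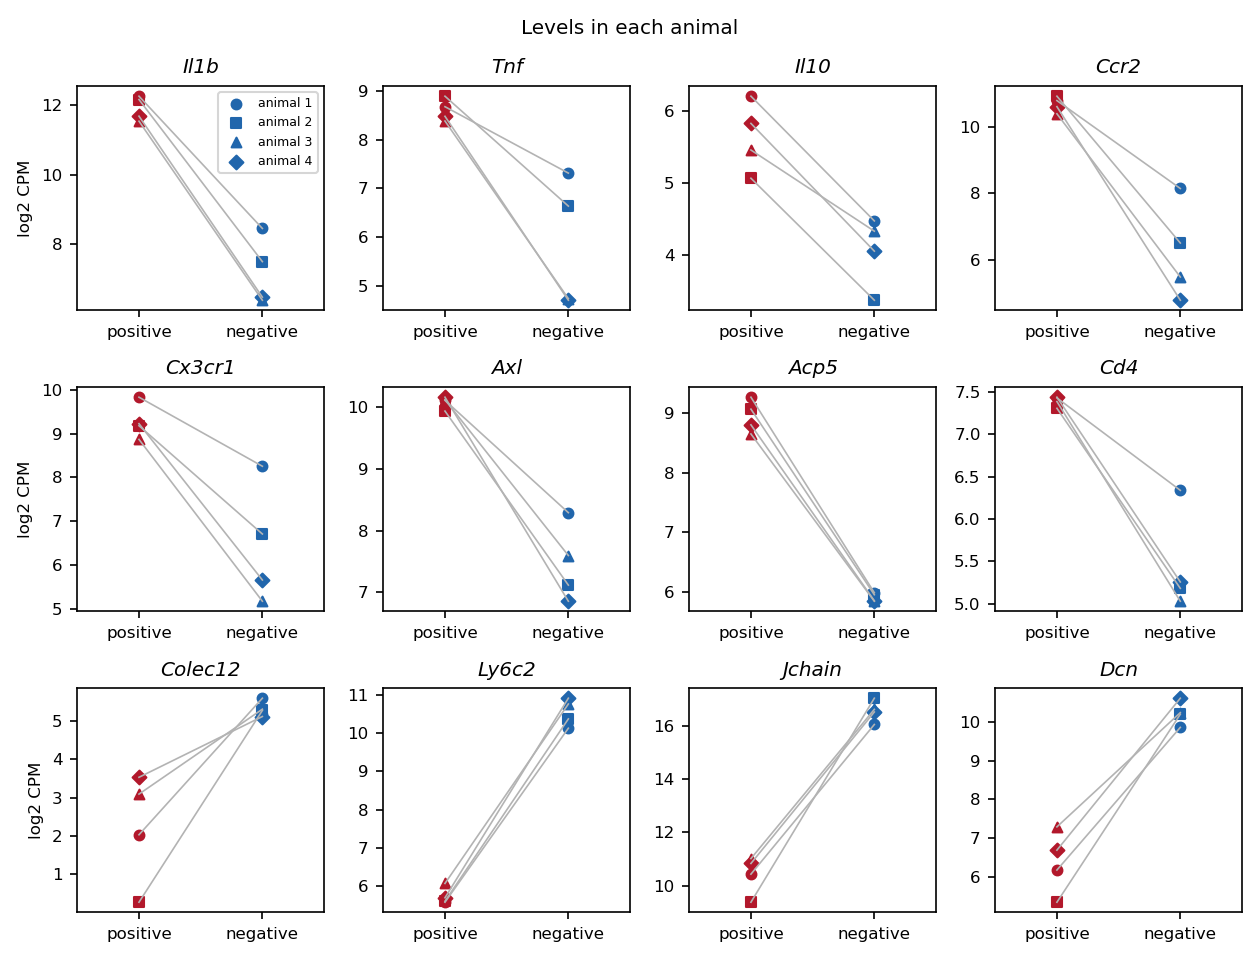
Log2 CPM of 12 genes in each library, red for GPR35-positive and blue for GPR35-negative, with a line and a symbol per animal. Il1b, Tnf, Il10, Ccr2, Cx3cr1, Axl, Acp5 and Cd4 are higher and Colec12, Ly6c2, Jchain and Dcn lower in the positive library of all 4 animals; with identity scaling Il10 (-0.88) and Cd4 (-0.37) turn negative.

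Antigen presentation and clearance lists also had medians above 0 in GPR35-positive cells, and below 0 with identity scaling. Of 18 genes of presentation by MHC class II 15 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 2.02 that became -0.16 with identity scaling (camera adjusted p = 1.35e-08, and adjusted p = 0.296 with an estimated correlation). The gene that was lower, H2-Eb2, was chosen after its values were seen. Those higher included the class II transactivator Ciita (2.62 ± 0.34), H2-DMb1 (2.78 ± 0.37) and the lysosomal protease Ctss (2.28 ± 0.27). Lysosome and lipid handling genes were higher for 19 of 25 (20 higher and 1 lower adjusted over the list alone), with a median of 1.27 that became -0.99 with identity scaling (camera adjusted p = 3.67e-07, and adjusted p = 0.296 with an estimated correlation). GPR35-negative replicate 1 stood at a mean of 7.39 log2 CPM for this list, against 6.69 to 6.81 in the others. Among the genes were the nuclear receptor Nr1h3 (2.87 ± 0.27), the cholesterol exporter Abcg1 (2.55 ± 0.31) and Soat1 (2.46 ± 0.32). Efferocytosis and scavenger receptor genes were higher for 12 and lower for 3 of 26 (12 and 3 adjusted over the list alone), with a median of 1.18 that became -1.14 with identity scaling (camera adjusted p = 5.72e-03, and adjusted p = 0.451 with an estimated correlation). The list's median was -0.02 in replicate 1 and 1.21, 2.29 and 1.89 in replicates 2 to 4, and GPR35-negative replicate 1 stood at a mean of 5.74 log2 CPM against 4.65 to 4.76 in the others. Havcr2, which encodes TIM-3, was higher (3.83 ± 0.43), as was Cd209a (4.70 ± 0.67), whose GPR35-positive replicate 1 stood at 29.0 CPM against 239 to 257 in the others. Alternative activation genes were higher for 11 and lower for 2 of 19 (12 and 3 adjusted over the list alone), with a median of 1.16 that became -1.13 with identity scaling (camera adjusted p = 0.0105, and adjusted p = 0.296 with an estimated correlation). The interleukin-13 receptor Il13ra1 was higher (1.80 ± 0.27). Tissue remodelling and angiogenesis genes were higher for 13 and lower for 5 of 27 (15 and 6 adjusted over the list alone), with a median of 0.90 that became -1.55 with identity scaling (camera adjusted p = 1.75e-03, and adjusted p = 0.296 with an estimated correlation). The collagenase Mmp13 (4.49 ± 0.28), Plaur (3.35 ± 0.29) and osteopontin, Spp1 (3.74 ± 0.41), were higher and Adamdec1 lower (-2.58 ± 0.23). Complement genes went both ways, with 8 higher and 6 lower of 19 and the same counts adjusted over the list alone. Their median was 0.81 (-1.62 with identity scaling) and mean 0.20, while the test pointed down (camera adjusted p = 0.95). GPR35-positive replicate 2 stood at a mean of 6.74 log2 CPM, against 7.38 to 7.47 in the others. Serping1 (-3.56 ± 0.29) and C1s1 (-3.40 ± 0.30), which stromal cells make, and Cd55 (-4.96 ± 0.57) were lower. Dendritic cell genes had 7 higher and 3 lower of 20 (9 and 3 adjusted over the list alone; median 0.91, and -1.63 with identity scaling; camera adjusted p = 0.149). They passed without replicate 1 (0.0236), without GPR35-positive replicate 1 (3.89e-03) and with identity scaling (1.98e-03). With all libraries the adjusted p = 0.577 with an estimated correlation, and the median in replicate 1 was -0.11. Dpp4 was higher (2.93 ± 0.40) and Irf4, also made by plasma cells, lower (-2.57 ± 0.23). With identity scaling Il13ra1 (-0.42) turned negative, and Ciita, H2-DMb1, Ctss, Nr1h3, Abcg1, Soat1, Plaur and Dpp4 lost their calls. B and plasma cell and stromal genes moved with these lists in the opposite direction.

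Of the metabolic lists, oxidative phosphorylation passed and the others did not. Oxidative phosphorylation genes were lower in GPR35-positive cells for 13 and higher for 1 of 28 (18 and 1 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 3.95e-03, and adjusted p = 0.502 with an estimated correlation). With identity scaling 28 of 28 were lower, at a median of -2.94, where the median of all genes was -2.51. Ndufa4 (-2.15 ± 0.20) and Ndufa1 (-1.99 ± 0.22), subunits of the respiratory chain, were lower. Glycolysis and hypoxia genes had 8 higher and 3 lower of 24 (8 and 4 adjusted over the list alone; median 0.18, -0.11 with library size only and -2.33 with identity scaling; camera adjusted p = 0.0751). They passed with the replicate block (0.0462; adjusted p = 0.530 with an estimated correlation), without replicate 3 (0.0430), without replicate 4 (0.0154), without GPR35-positive replicate 3 (0.0482) or 4 (0.0330), and without GPR35-negative replicate 4 (0.0336). Pfkfb3 (2.38 ± 0.37, with GPR35-positive replicate 1 at 158 CPM against 107 to 111 in the others), Hif1a (1.53 ± 0.26) and Hk2 (1.68 ± 0.31) were higher. Of 16 lysophosphatidic acid metabolism genes 1 was higher and 4 lower (1 and 4 adjusted over the list alone; median -0.13, and -2.70 with identity scaling; camera adjusted p = 0.329, and 0.0394 with the replicate block; blocked adjusted p = 0.284 with an estimated correlation). The phospholipase Pla2g4a was higher (1.66 ± 0.26), and Enpp2, autotaxin (-3.00 ± 0.61), and Plpp3 (-3.31 ± 0.59) were lower. Tryptophan and kynurenine genes had 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone; median 0.36, and -2.02 with identity scaling; camera adjusted p = 0.393). The aryl hydrocarbon receptor Ahr (1.97 ± 0.32) and kynureninase, Kynu (3.96 ± 0.90, with 0 counts in GPR35-negative replicate 4), were higher. Ido1 (-4.45 ± 1.01) and Afmid (-1.17 ± 0.29), enzymes of the kynurenine pathway, were lower, but Afmid lost its call without replicate 2 (edgeR adjusted p = 0.0577), 3 (0.0715) or 4 (0.0654). Of 6 tested glucocorticoid synthesis genes 1 was higher and 2 lower (1 and 2 adjusted over the list alone; median -0.53, camera adjusted p = 0.342). Hsd11b1, which makes corticosterone from its inactive 11-keto form, was at 3.06 ± 2.08 against 85.5 ± 16.5 CPM (-4.80 ± 0.50) and Fdx1 was lower (-1.06 ± 0.20). Hsd11b2 was not past the threshold (-1.55 ± 1.71) and read 0.45 without GPR35-negative replicate 3. With identity scaling Hif1a (-0.88), Hk2 (-0.63), Pla2g4a (-0.62) and Ahr (-0.38) turned negative, and Pfkfb3 and Kynu (adjusted p = 0.108) lost their calls. Plasma cell and stromal genes were lower in GPR35-positive cells in the same libraries.

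Proliferation genes were lower in GPR35-positive cells, while stress response lists had medians above 0, and below 0 with identity scaling. Cell cycle genes were lower for 20 and higher for 1 of 29 (21 and 1 adjusted over the list alone). Their median was -1.25 (camera adjusted p = 5.14e-06, and adjusted p = 0.413 with an estimated correlation). With identity scaling 29 of 29 were lower, at a median of -3.795. The genes that were lower included Rrm2 at -2.54 ± 0.25, Ccna2 at -1.66 ± 0.23 and Ube2c at -3.04 ± 0.54. The gene that was higher, Mcm3, was chosen after its values were seen. Genes of dissociation and immediate early response were higher for 14 and lower for 1 of 22 (18 and 1 adjusted over the list alone), with a median of 0.83 that became -1.58 with identity scaling (camera adjusted p = 2.81e-05, and adjusted p = 0.296 with an estimated correlation). Among them were Nr4a1 (1.48 ± 0.17), Btg2 (1.46 ± 0.20) and Maff (1.72 ± 0.25). Heat shock genes were higher for 10 of 16 (11 adjusted over the list alone), with a median of 0.67 that became -1.76 with identity scaling (camera adjusted p = 2.92e-03, and adjusted p = 0.413 with an estimated correlation). Among them were Bag3 (1.76 ± 0.26) and Hspa8 (0.88 ± 0.17). With identity scaling Nr4a1 (-0.92), Btg2 (-0.99), Maff (-0.75), Bag3 (-0.53) and Hspa8 (-1.50) turned negative. With identity scaling, under which the median of all genes was -2.51, the calls of both lists ended (camera adjusted p = 0.232 and 0.848). In the same libraries the B and plasma cell genes, at a median of -5.32, were lower in GPR35-positive cells.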

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

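Chosen only after the results were seen were the tests of RNA from other cells, of lower expression in macrophages, of dendritic cell RNA and of the 56 genes below the identity bound, as were the scaling to identity genes and thinning.

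Of 350 groups of 4 libraries checked for a value far from the others, 12 held one, where chance gives about 1 in 20, or 17.5. In GPR35-negative replicate 4, Itgax was at 0.033 CPM (others 8.32 to 12.3), Dnase1l3 at 1.10 (4.64 to 6.21) and Kynu at 0 (2.02 to 3.63). Cd209a was at 29.0 CPM in GPR35-positive replicate 1 (239 to 257) and Pfkfb3 at 158 there (107 to 111). Nfkb1 was at 19.4 CPM in GPR35-negative replicate 3 (27.1 to 29.1), Usp18 at 29.3 in GPR35-positive replicate 3 (35.4 to 36.7) and Nkg7 at 7.79 in GPR35-negative replicate 1 (10.8 to 11.6). As means of log2 CPM, the IL-10 pathway list was at 7.89 in GPR35-positive replicate 1 (7.45 to 7.47), the complement list at 6.74 in GPR35-positive replicate 2 (7.38 to 7.47), and in GPR35-negative replicate 1 the efferocytosis list was at 5.74 (4.65 to 4.76) and the lysosome list at 7.39 (6.69 to 6.81).

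Macrophage identity genes were lower and B and plasma cell, T and innate lymphoid, stromal, epithelial, and glial and erythroid lists higher in the GPR35-negative libraries, while granulocyte and dendritic cell lists did not pass. The identity list kept a median of 2.01 after thinning. Its mean was at least 6.4 log2 CPM in each library, and thinning hardly moves the ratio of genes this abundant. The list took 3.66% to 4.02% of counts in the positive and 0.582% to 2.22% in the negative libraries. Such a share does not scale with the number of reads. These values argue against read depth as the cause for the identity genes. They do not bear on the amount of RNA that entered each library. Lower expression per macrophage, or a lower macrophage share that raises all other types alike, would move the other lists by 1 common factor. The epithelial and B and plasma cell medians lay 3.95 apart (2.26 to 5.25 per animal), which argues against either as the whole cause. Only 6 of 22 epithelial genes reached 10 CPM in the positive libraries, so low counts may have narrowed their ratios. The stromal median, with 18 of 24 genes at that level, was -2.77 against -5.32 for B and plasma cells. A candidate source is RNA of other cells. The highest of the B and plasma, epithelial and stromal medians was -1.37. Jchain, Xbp1, Col3a1 and Epcam were higher in the negative library of all 4 animals. Jchain was at 10.9%, Xbp1 at 3405 ± 457 CPM and Col3a1, chosen after its values were seen, at 2506 CPM. These values restate the pattern, so they lend this source no support of their own. The gate on MHC class II and CD64 is meant to leave out plasma, stromal and epithelial cells, but its purity was not assessed here. Both populations came through it, and Jchain still took 7.37% to 14.1% of counts in the GPR35-negative libraries. Of the 14 B and plasma, 24 stromal and 22 epithelial genes tested, 7, 18 and 6 reached 10 CPM in the positive libraries. Of those listed, 0, 1 and 0 are in another list. Whether whole cells, adhering fragments or free RNA brought these transcripts was not tested, and a difference between the macrophages stays open.

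Scaled to the identity genes, 84 genes stayed higher in GPR35-positive cells, 75 of them also with the block. After thinning, 92.9% of the 84 (78) kept their call. Thinning only removes reads, so it cannot show whether near-zero counts in the GPR35-negative libraries gave some of these calls. Dilution of unchanged macrophages cannot be told apart for the 84 genes as a set: 33.3% (28 genes) lay above the most reduced identity gene in every animal. The exact interval of 23.4% to 44.5% includes the bound of 25% set in advance, but takes genes as independent, which they are not. The median of the other 56 lay above the most reduced identity gene in 2 of 4 animals. RNA of dendritic cells, which the CD64 gate is meant to leave out, cannot be told apart either. The list's identity-scaled median of -1.63 covers members that went both ways, among them Cd209a at 2.09 (195 ± 111 CPM) and Irf4 at -5.03. Set against all genes the list was higher (camera adjusted p = 1.98e-03). Of its 20 genes 17 reached 10 CPM in the positive libraries and 5 are in another list. Counted in either direction, as many genes higher in 1 group came from 5 of the 35 splits. By the rule set in advance chance is then not excluded. The highest other, 8982, were genes lower in the group with the higher identity level, where the real split had 11957. The rule set these against the 84 higher genes, an unlike direction, so it decides nothing. Counted only toward the group with the higher identity level, a choice made afterwards, the highest other was 1 against 84. The 4 other splits, which point to a structure of the samples, were among the 16 that had 3 GPR35-positive libraries on 1 side.

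Relative to the identity genes, long-lived resident macrophage genes were lower in GPR35-positive cells (0 higher and 16 lower of 20; median -2.33), as was the median gene (-2.51). Stromal and lymphatic cells that share such genes cannot be told apart as a source. In advance, 8 members were taken to be rarely expressed by these cells, which was not checked here and may not hold for each, Mrc1 among them. The 7 tested (Cd163, Timd4, Folr2, Cd209f, Fcna, Cbr2 and Mrc1) lay at -2.31 to -3.48 from the identity median, past the bound set in advance. A typical gene lies there too, so that bound decides nothing. Without scaling, the 7 had medians of -2.43, -0.99, 0.85 and 0.29 in replicates 1 to 4, below the median gene in 2 of 4 animals. With replicates 1 and 2 alone the resident list passed (camera adjusted p = 1.85e-04), a setting for which no estimated correlation was run. With all libraries, camera with an estimated correlation gave the list an adjusted p = 0.986. The list's medians in replicates 3 and 4 were 1.14 and 0.63. That GPR35-negative cells hold relatively more resident-like macrophages stays open and was not tested.

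As many genes past the edgeR threshold (5387) came from 1 of the 35 splits of the 8 libraries into 4 and 4, the highest other being 0. That share, the smallest possible, is under the 0.05 set in advance, but only 8 of the splits part all 4 pairs. The real one was the 1 of these 8 with as many genes. They are too few for a share under 0.05, so chance is not excluded within animals. As many lists (21) came from 5 splits, the highest other being 25, so chance is not excluded for the count of lists. Each of the other splits among these 5 had 3 GPR35-positive libraries on 1 side, and so kept part of the real contrast. Of the 8 splits that part all 4 pairs, 3 gave as many lists.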

How the results depend on the processing

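The identity scalings, thinning and the use of replicates 1 and 2 alone were chosen after seeing the data. Gpr35 kept its direction and call under all settings run. Across planned scalings, filters and tests the count of genes ran from 4894 (filter of 5 CPM) to 6908 (DESeq2 with the replicate block); the replicate block gave 5580, 4975 of them shared with the fit without it in the same direction, and among the 140 named genes and the lists it changed no other call than those of the 4 lists named in the text and of Cbr2 (adjusted p = 0.0666). Library size only gave 1690 higher and 4193 lower, and moved the median of all genes to -0.34, upper-quartile scaling to -0.19 and identity scaling to -2.51, from -0.05. Leaving out an animal or library gave 3281 to 5971 genes, 1569 to 2931 higher and 1681 to 3040 lower, with fewer samples; the lowest were without replicates 3 (3281) and 4 (3306). Replicates 1 and 2 alone gave 1243 genes (489 higher, 754 lower; 1209 shared), again with fewer samples, and ended the efferocytosis (0.167) and oxidative phosphorylation (0.127) calls while the resident and glycolysis lists passed (1.85e-04 and 1.53e-03). Thinning gave 5417 genes, 5157 of them shared. Camera with an estimated correlation gave 0 lists, against 21, and 3 at an unadjusted p under 0.05; fry gave 26. Library size only also took the chemokine (0.0244) and receptor (0.0157) lists past the threshold, as did upper-quartile scaling (0.0329), the filter of 5 CPM (0.0413) and identity scaling without (2.52e-04) and with (0.0209) the block for the receptors. The difference in genes with a count, -39.3, changed sign between leave-outs (-234 to 201).

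Identity scaling gave 12041 genes (84 higher, 11957 lower), and 11278 with the replicate block (111 higher, 11167 lower); by construction it sets the mean level of the identity genes equal in each library. Of 140 named genes 82 kept direction and call, 26 lost the call and 32 reversed: Spi1 -0.0539, Cd4 -0.37, Selenop -0.91, Socs3 -0.42, Tgfb1 -0.17, H6pd -1.60, Lpar6 -0.47, Pla2g4a -0.62, Ahr -0.38, Ifi30 -0.43, Il13ra1 -0.42, Klf4 -1.64, Pparg -1.13, Myd88 -0.72, Irak4 -0.95, Nfkb1 -1.51, Irf8 -0.21, Gbp3 -0.36, Usp18 -0.78, Ctsz -0.94, Hif1a -0.88, Hk2 -0.63, Vegfa -0.33, Nr4a1 -0.92, Btg2 -0.99, Maff -0.75, Bag3 -0.53, Hspa8 -1.50, Hspa1a -1.28, Hspa1b -1.34, Wdfy4 -1.30 and Il10 -0.88. Reversed here means that the sign changed with the common shift of the scaling, whether or not the new value was past the threshold. Hsd11b2, not past the threshold, ran from -2.13 to 1.38 over the leave-outs. The cause of that range was not tested. Voom ended the calls of 5 named genes and leaving out replicate 2 or 4 those of 12 and 15. In simulated counts a log2 change of 1 was recovered for 24% of genes, and for 0% with animal effects. Those counts held 50 changed genes per size, and the adjusted threshold depends on how many genes change. In the data 5387 genes passed, of which 1545 were higher and 2006 lower by at least 2-fold, so smaller differences were called too. The simulated shares therefore do not give the smallest difference detectable here.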

Other observations

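The genes and values here were chosen after the data were seen. Genes above the most reduced macrophage identity gene in every animal, 28 in all, included H2-M2 (identity-scaled log2 fold change 3.88), Treml4 (4.19), Itgax (3.62), Mefv (3.71), Mmp12 (3.51), Gpr141 (3.25), Il1b (2.47), Mmp13 (2.25), Ccr2 (2.12), Cd209a (2.09) and Havcr2 (1.77).

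Xist, the transcript of an inactive X chromosome, was at 26.6 CPM in GPR35-negative replicate 3 and 2.78 in GPR35-positive replicate 3, at 2.52 and 0.22 in the negative and positive libraries of replicate 4, and at most 0.0665 in those of replicates 1 and 2. The Y-linked Ddx3y lay between 41.7 and 103 CPM in all 8 libraries, whose animals the labels give as male. These CPM values use library totals without TMM factors. Whether the libraries of replicates 3 and 4 hold RNA of another animal was not tested, and it stays open for their values and their pairing. The animals of replicates 1 and 2 alone gave 1243 genes past the threshold.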
